A study of Drosophila melanogaster with 3 samples.

How the data were processed

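E(z)-GFP was mapped by chromatin immunoprecipitation and sequencing in 3 biological replicates of whole prepupae, which form 1 group per the labels. The labels give an anti-GFP precipitation in the sample description and E(z) as the antibody field, and the description was followed. The authors deposited, for dm6 and for dm3, a relaxed list of 30000 peaks and background regions per replicate, a relaxed list from the pooled alignments and an optimal list thresholded on the irreproducible discovery rate. Per the submitters' text deposited with each sample, each replicate list was derived from that replicate's alignment and 1 further file whose kind is not stated there, and the optimal list from the replicate lists and the pooled list. The labels name a possible control experiment, which was not used here. The peak caller, the aligner and their versions are not given in the sources used here. The signal values that the authors deposited have no stated scaling for depth, and were used only to rank peaks within a list. The authors also deposited -log10 q-values per peak, which were only described, and summit offsets, which placed the summits. In the optimal dm6 list the -log10 q-values that the authors deposited ran from 2.87 to 3.97. Depth per sample is unknown from these lists, so no precision was derived from it, and intervals cover counting error of peaks or genes only. The text files with the samples were read for this description and not used for values. All 5623 optimal dm6 peaks were in the pooled list with the same signal value and were its highest-ranked peaks. Of these, 16 repeat the interval of a higher-ranked peak and differ from it in summit, so peaks were identified by summit.

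Genes were taken from Ensembl release 115, assembly BDGP6.54, and sequence from the RefSeq copy of genome release 6. On the 6 arms every dm6 peak ended within the reference length, and 13943 of 13944 genes with a shared symbol had the same coordinates in both annotations. The background held 13945 protein-coding genes on the arms with 19607 TSSs, and 41 genes elsewhere were left out. For the transfer RNA list the background was all annotated genes on the arms except transposable elements. Across the 22 gene lists, 4 symbols were matched through a synonym and 2 had no match, and those 2 are not reported here. Coordinates are 1-based dm6. No annotation of dm3 was used here, and dm3 lists entered counts, overlaps and shares of the arms only. For those shares the length of each dm3 arm was taken as its highest peak end in the relaxed lists.

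Named genes followed a rule fixed before the data were examined. They were the gene of the nearest TSS of the 25 highest-signal optimal peaks found in all 3 replicates, all 8 Hox genes, E(z), and for each list up to 4 members with the highest signal and up to 2 members without a summit, in alphabetical order. A gene's rank in a replicate was that of its best peak within 1 kb of a TSS in the relaxed list, and mean ranks cover the replicates with such a peak.

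An optimal peak was found in a replicate when its summit lay inside one of the replicate's 5623 highest-signal peaks. Promoter shares were tested with 1000 circular shifts along each arm. The same shifts were run for shared peaks, and their p is not used, because the optimal list was derived from these replicates. Arms were tested with exact binomial tests and gene lists with Fisher's exact tests, two-sided, with Benjamini-Hochberg adjustment over 6 arms and over 22 lists and a threshold of 0.05. Intervals of odds ratios are normal intervals on the log scale with 0.5 added to each count. Hox clusters were compared with 100000 random windows of the same length. Motifs were compared between the window of 250 bp each side of a summit and a window 2 kb away that overlapped no pooled peak, with a two-sided exact McNemar test adjusted over 6 motifs. The design named windows on each side, and the paired test took 1 usable side per summit, drawn at random with seed 20. A usable window was found for 4528 of 5623 summits. Ratios of discordant pairs, odds ratios of words and the nearest-gene share of strong peaks were added after seeing the data. So was the contrast of ribosomal protein genes with proteasome and respiratory chain genes together.

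Alternatives fixed before the data were examined were the top 1000 and top 2N peaks, summits within 200 bp, reciprocal overlap of 50%, distances of 500 bp and 5 kb, the 2811 peaks of higher signal, peaks found in all 3 replicates, each replicate left out (optimal peaks found in both others, 3550, 3473 and 4080 without replicates 1, 2 and 3), gene bodies, the nearest gene within 5 kb, 10000 circular shifts in place of Fisher's test, gene numbers as expectation for arms, clusters extended by 20 kb, windows of 100 bp each side, promoters matched in GC content within 2 percentage points, all pooled peaks for the rank correlation, and dm3. TSSs of all annotated genes and the control window on the other side were chosen after seeing the data. Gene list tests were tested on simulated data over 13945 genes, where 10 of 10 planted lists and 0 of 10 null lists were called. Each list had 80 genes, and a large share of each planted list was given a summit. Shorter lists, weaker excess and low shares were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.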

Results

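Chromatin immunoprecipitation followed by sequencing was used to map E(z) in whole fly prepupae. E(z) is the histone methyltransferase subunit of Polycomb repressive complex 2, which keeps developmental genes silent. The flies carried a transgene for E(z) fused to green fluorescent protein (GFP), and the fusion was precipitated with an antibody against GFP, per the labels. The labels name 3 biological replicates of this 1 group, from pooled males and females, so every comparison was between replicates or between parts of the genome. Each replicate had a relaxed list of 30000 peaks on dm6, and a pooled list of 30000 peaks came from the replicates together. The authors' list of peaks that passed their reproducibility threshold, called the optimal list below, held 5623 peaks with a median width of 424 bp. Sequencing depth is unknown from these lists, and the authors' signal value of a peak was used only to rank peaks within a list.

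The replicates shared most of their strong peaks, and replicates 1 and 2 were closer to each other than to replicate 3. Each replicate's 5623 highest-signal peaks were compared with the optimal list. The summits of 84.1% of the optimal peaks lay inside such a peak of replicate 1, 83.2% in replicate 2 and 73.5% in replicate 3 (mean 80.3% ± 5.90, SD, n = 3). In all, 3141 optimal peaks (55.9%) were found in all 3 replicates, and 84.9% with the top 2N peaks. The optimal list was derived from these same replicates, so these shares describe it and are no independent test of sharing. The strong lists of replicates 1 and 2 overlapped by 75.6%, those of 1 and 3 by 63.3% and those of 2 and 3 by 65.6% (mean 68.2% ± 6.5, SD over 3 pairs). Spearman's rho of the ranks of shared optimal peaks was 0.759 for replicates 1 and 2, 0.537 for 1 and 3 and 0.620 for 2 and 3. These correlations run across peaks, which are not independent replicates, so no p-value was computed. In the relaxed lists, 93.3% of the optimal peaks were present in all 3 replicates.

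The strongest peaks lay near genes of varied function, and 0 of the 25 strongest peaks found in all 3 replicates had a Hox or developmental transcription factor gene from the fixed lists as the nearest gene. Of the 541 peaks found in all 3 replicates among the 563 strongest, 27 (4.99%) had such a nearest gene, which gives 1.25 expected among 25 and a binomial probability of 0.278 for none, so the count decides nothing. It covers members of the fixed lists only, and developmental regulators outside those lists were not counted. The first peak, at chromosome X 2703680 to 2704083, was 18 bp upstream of the start of Ugalt, a UDP-galactose transporter gene, and ranked 1 in each replicate. The second, at 3L 19590433 to 19590810, lay 113 bp upstream of CG14100. The third, at 2L 480887 to 481292, was 1397 bp upstream of cbt, inside an intron of ush, and had a mean rank of 3.67 ± 1.15 (SD, n = 3). A peak in the UTR of PNPase, which encodes a mitochondrial RNA exonuclease, was at 3R 31404481 to 31404850 and had a mean rank of 4.33 ± 0.577 (SD, n = 3). The nearest TSS of further peaks among the 25 belonged to CG11050, CenG1A, CG32772, the kinase gene Lk6, CG13323, Chro, which encodes a chromosomal protein, larp, eEF1gamma, osa, a trithorax group gene, and CG31668. That of the others belonged to Hsp27, a small heat shock protein gene, mRpL41, CG18549, CG16753, Art3, CG13921, CG9663, CG1888, rib, chinmo and CG43245. The osa peak, at 3R 17704221 to 17704591, was in an intron of osa, 13939 bp from the nearest annotated start. The summits assigned to CG13323, chinmo, eEF1gamma and CG16753 were also distant, at 11978, 6821, 5723 and 5716 bp, the last inside an intron of CG32486. The Hsp27 peak, at 3L 9383721 to 9384110, was 143 bp upstream of the gene, with a mean rank of 16.3 ± 3.21 (SD, n = 3). Of the 25 summits, 14 were within 1 kb of a transcription start site (TSS) and 11 within 250 bp.

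Peaks lay at promoters more often than shifted peaks did. Of the 5623 optimal summits, 2293 (40.8%, exact 95% interval 39.5% to 42.1%) were within 1 kb of an annotated TSS of a protein-coding gene. The mean of 1000 circular shifts was 20.3% and the highest 23.9% (one-sided permutation p = 0.001, the smallest the shifts can give). Introns away from a TSS held 2069 summits (36.8%), UTRs 44, coding exons 11, and 1206 summits (21.4%) lay outside protein-coding genes. In the equally long lists of the replicates the promoter share was 39.3% in replicate 1, 41.3% in replicate 2 and 49.7% in replicate 3 (mean 43.4% ± 5.49, SD, n = 3). Within 5 kb the share of optimal summits was 70.6%, against a mean of 53.9% for shifted peaks.

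Chromosome 4, the small arm rich in heterochromatin, held fewer peaks than its length would give, and the deficit was smaller against its number of genes. It had 20 optimal peaks, 0.356% of the total against 1.01% of the length (exact binomial test, adjusted p = 1.98e-07), and 13.4 ± 2.67 peaks per Mb (SD, n = 3) in the replicates' lists. Against its share of genes, 0.574%, the adjusted p was 0.0405 (exact binomial test). Arm 2R held 17.3% of the peaks against 18.9% of the length (exact binomial test, adjusted p = 0.00613), and 39.0 ± 2.33 peaks per Mb (SD, n = 3) in the replicates' lists. Here and below, leaving out a replicate means keeping only the optimal peaks found in both other replicates, which lowers the number of peaks and still rests on a list made from all 3. The call for 2R was lost among the peaks found in all 3 replicates, without replicate 1, without replicate 2 and on dm3. The shares of X (18.4%), 2L (18.0%), 3L (22.1%) and 3R (23.9%) did not pass the test. With the share of genes as expectation X and 3L did (exact binomial test, adjusted p = 4.39e-07 and 7.77e-06), as did X without replicate 3 (adjusted p = 0.0272, exact) and 3L on dm3 (adjusted p = 0.0156, exact). On those arms the optimal list held 43.8, 43.1, 44.3 and 41.8 peaks per Mb.

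Genes of the Polycomb target type carried summits far more often than other genes. All 8 Hox genes, which set segment identity, had an optimal summit within 1 kb of a TSS, against 16.1% of other protein-coding genes (Fisher's exact test, adjusted p = 2.06e-06). In the replicates' lists the Hox share was 75.0%, 75.0% and 100% (mean 83.3% ± 14.4, SD, n = 3). Among the optimal peaks found in all 3 replicates, and without replicate 2, 5 of 8 Hox genes (62.5%) had a summit, and the call was kept. Of 85 developmental transcription factor genes, 70 (82.4%) had one, against 15.7% of other genes, an odds ratio of 24.98 (95% interval 14.0 to 42.3, adjusted p = 4.73e-40 by Fisher's exact test). The strongest were at cad, a posterior patterning gene with a best rank of 122 ± 89.6 (SD, n = 3), lbe at 192 ± 141, NK7.1 at 235 ± 44.2 and Poxm at 316 ± 234. The factor genes bab1 and bap had no optimal summit, and their best peaks ranked 12637 and 9696 on average. Signalling ligand genes had summits at 11 of 21 (52.4%, odds ratio 5.73, Fisher's exact test, adjusted p = 4.33e-04). They included spi, an epidermal growth factor ligand, and wg, the Wnt ligand, at mean ranks of 356 ± 242 and 510 ± 359 (SD, n = 3), and pyr and bnl, fibroblast growth factor ligands, while gbb and grk had no peak within 1 kb in the relaxed lists. The ligand call was lost among the peaks found in all 3 replicates (23.8%, Fisher's exact test, adjusted p = 0.116), and the share was 28.6% without replicate 2 (adjusted p = 0.0448 by Fisher's exact test) and 33.3% without replicate 3 (adjusted p = 0.0222 by Fisher's exact test).

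Factors that bind Polycomb response elements, the DNA sites that recruit Polycomb complexes, had summits at 6 of 11 of their own genes (54.5%, odds ratio 6.24, Fisher's exact test, adjusted p = 0.00998), a call lost at 500 bp. Adf1 had a mean rank of 53.0 ± 21.9 (SD, n = 3), followed by Trl, which encodes GAGA factor, at 414 ± 168, Dsp1 at 543 ± 226 and lolal at 1131 ± 541. The genes cg and pho had no optimal summit. The list of ecdysone response genes holds genes that answer the moulting hormone and some, such as dib, that serve to make it. Its genes had summits at 17 of 30 (56.7%, odds ratio 6.83, Fisher's exact test, adjusted p = 2.06e-06). The highest were E23, an ecdysone-induced transporter gene, at a mean rank of 226 ± 99.2 (SD, n = 3), and Eip75B, an ecdysone-induced nuclear receptor gene, at 794 ± 144, with Eip63F-1 and Eip63E below them, and crol and dib had none. The ecdysone share was 26.7% in the higher-signal 2811 peaks and 33.3% among the peaks found in all 3 replicates, and the call was kept.

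Several other lists of regulators did not pass Fisher's test at 1 kb, and 3 of them passed under other settings. Polycomb group genes had summits at 6 of 21 (28.6%, adjusted p = 0.174 by Fisher's exact test), among them ph-p at a mean rank of 37.7 ± 4.93 (SD, n = 3), jing at 58.7 ± 44.6, Su(z)2 at 332 ± 208 and Psc at 834 ± 589, while Asx and Caf1-55 had none. Trithorax group genes, which oppose Polycomb repression, had 5 of 15 (33.3%, adjusted p = 0.110 by Fisher's exact test), at brm, fs(1)h, skd, tna and, named after its values were seen, mor. The brm peak ranked 237 in the optimal list and was within 1 kb of the TSS in replicate 1 only, and ash1 and ash2 had none. Proneural and E(spl) genes had 7 of 20 (35.0%, adjusted p = 0.0536 by Fisher's exact test), led by E(spl)mdelta-HLH at a mean rank of 702 ± 236 (SD, n = 3), with E(spl)m2-BFM, hry and E(spl)m7-HLH, and without ac and amos. Cell cycle genes had 4 of 19 (21.1%, adjusted p = 0.651 by Fisher's exact test), at Dp, stg, Cdk4 and dap, and none at aurA and aurB. Polycomb group genes passed against circular shifts, 28.6% against a mean of 8.48% (permutation, adjusted p = 0.0356). Shifted peaks lie at promoters less often than optimal peaks, so passing there does not show more summits than at other genes (16.1%). Trithorax genes passed with gene bodies (60%, Fisher's exact test, adjusted p = 0.00346), while in the higher-signal peaks their direction turned, 6.67% against 9.91% of other genes. A longer gene body has more room for a summit, and the gene body tests took no account of length. The direction for cell cycle genes turned at 500 bp and without replicates 2 and 3, at 10.5% each. Proneural and E(spl) genes passed at 5 kb, with gene bodies and in the higher-signal peaks (Fisher's exact test, adjusted p = 0.00807, 0.0380 and 0.0236). They also passed against circular shifts, with a shifted mean of 7.31% (permutation, adjusted p = 0.0176), where the limit of shifted peaks holds as well.

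A higher share of ribosomal protein genes held summits than of genes of the proteasome and the respiratory chain. These lists hold every gene with a matching symbol, Prosalpha1R among them, and transcription of their members was not measured here. Ribosomal protein genes had summits at 46 of 92 (50%, odds ratio 5.28, 95% interval 3.51 to 7.95, Fisher's exact test, adjusted p = 4.90e-13), highest at RpS19b with a mean rank of 119 ± 40.7 (SD, n = 3), then RpS27, RpS10b and RpL24, and none at RpL10Aa and RpL10Ab. In replicates 1, 2 and 3 the ribosomal share was 48.9%, 48.9% and 66.3%. Proteasome genes had 2 of 48 (4.17%, adjusted p = 0.0328 by Fisher's exact test), at Rpn5 and Rpn13 and not at Prosalpha1 or Prosalpha1R, and respiratory chain genes 12 of 80 (15%, adjusted p = 1.00), with ND-ASHI, ND-MWFE, ND-75 and ATPsynE highest and ATPsynB and ATPsynbeta without. The difference between ribosomal protein genes and the latter lists together (10.9% of 128 genes) had an odds ratio of 8.14 (Fisher's exact test, unadjusted p = 2.01e-10). This contrast was not among the tests fixed beforehand. It joined lists whose shares had been seen, so its p describes the gap and gives no independent support. Top-expressed cytoskeleton and translation genes had 6 of 12 (50%, adjusted p = 0.0148 by Fisher's exact test), at Gapdh2, a glycolytic enzyme gene with a mean rank of 41.3 ± 13.2 (SD, n = 3), Act5C, Pgk and eEF1alpha1 among others, and not at Act42A or Ald1. That call was lost without replicate 1, without replicate 3, among the peaks found in all 3 replicates, in the higher-signal 2811 peaks and with each peak given to its nearest gene. Transfer RNA genes had 32 of 290 (11.03%, against 15.3% of other annotated genes, adjusted p = 0.0748 by Fisher's exact test), with tRNA:Tyr-GTA-1-7, tRNA:Tyr-GTA-1-8, tRNA:Val-TAC-1-1 and tRNA:Gln-TTG-2-1 highest and none at tRNA:Ala-AGC-1-1 or tRNA:Ala-AGC-2-10. Both tyrosine genes had the same best peak, of optimal rank 167. Neighbouring transfer RNA genes can thus share a summit, while Fisher's test treats them as independent. The share of transfer RNA genes was 17.9% in replicate 3 against 9.31% and 8.28% in replicates 1 and 2. The lower share of transfer RNA genes passed in 7 of 10 alternatives, and the direction turned at 5 kb, 40.7% against 32.4% (Fisher's exact test, adjusted p = 0.00872), and against circular shifts, 11.03% against a mean of 7.22% (permutation, adjusted p = 0.205). Respiratory chain genes likewise lay above the shifts, at a mean of 7.76% (permutation, adjusted p = 0.0728). Shifted peaks lie at promoters less often than optimal peaks, so both shifted means are lower than the shares of other genes.

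Chemoreceptor genes carried few summits, and the calls for low shares of other tissue-restricted families depended on the test and the setting. Chemoreceptor genes had 4 of 179 (2.23%, odds ratio 0.117, Fisher's exact test, adjusted p = 1.49e-08), at Ir94h, Ir48b, Gr77a and Ir67c, with Gr10a and Gr10b among those without. Cuticle protein genes had 5 of 122 (4.10%, adjusted p = 2.10e-04 by Fisher's exact test), at Cpr72Eb, Cpr62Ba, Cpr47Ec, Cpr73D and, named after its values were seen, Edg84A, and not at Acp65Aa or Ccp84Aa. Gut protease genes, such as alphaTry and betaTry, had 0 of 26 (adjusted p = 0.0308 by Fisher's exact test), and testis genes, such as achi and aly, had 0 of 34 (adjusted p = 0.00998). Against circularly shifted peaks, the low shares of cuticle, gut protease, testis and proteasome genes no longer passed (permutation, adjusted p = 0.437, 0.594, 0.232 and 0.652), and chemoreceptor genes did (permutation, adjusted p = 0.02). The shifted means of the former were 7.54%, 7.14%, 8.24% and 7.44%, against 16.2% to 16.3% of other genes. Shifted peaks favour promoters less, so this test asks a different question from the comparison with other genes. The chemoreceptor call was kept in 10 of 10 alternatives, with shares from 0.559% to 13.4%, and the cuticle call was lost at 5 kb (23.8%). The testis and proteasome calls were each lost in 9 of 10 alternatives and the gut protease call in 7 of 10. For testis genes these included 5 kb, gene bodies and the nearest gene only. All 3 calls were lost in the smaller sets without replicate 1, 2 or 3. Gut protease and testis genes stayed at 0% there while the share of other genes fell to between 11.04% and 12.06%, so these losses cannot be put down to a replicate. Heat shock genes had 5 of 15 (33.3%, adjusted p = 0.110 by Fisher's exact test), at Hsp27, Hsp83, Hsp26, Hsp22 and, named after its values were seen, Hsp23, and not at Hsp60A or Hsp67Ba, and they passed without replicate 2 (adjusted p = 0.0423 by Fisher's exact test). The shares of muscle, neuronal and fat body genes were near that of other genes, and their direction turned in several alternatives. Muscle genes had 3 of 22 (13.6%), at Zasp52, sls and Tm1 and not at Act57B or Act79B. Neuronal genes had 3 of 18 (16.7%), at elav, Syx1A and futsch and not at Appl or brp, and fat body genes 2 of 13 (15.4%), at bmm and FASN1 and not at Acbp2 or apolpp (adjusted p = 1.00 for each by Fisher's exact test).

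**Figure D1:**
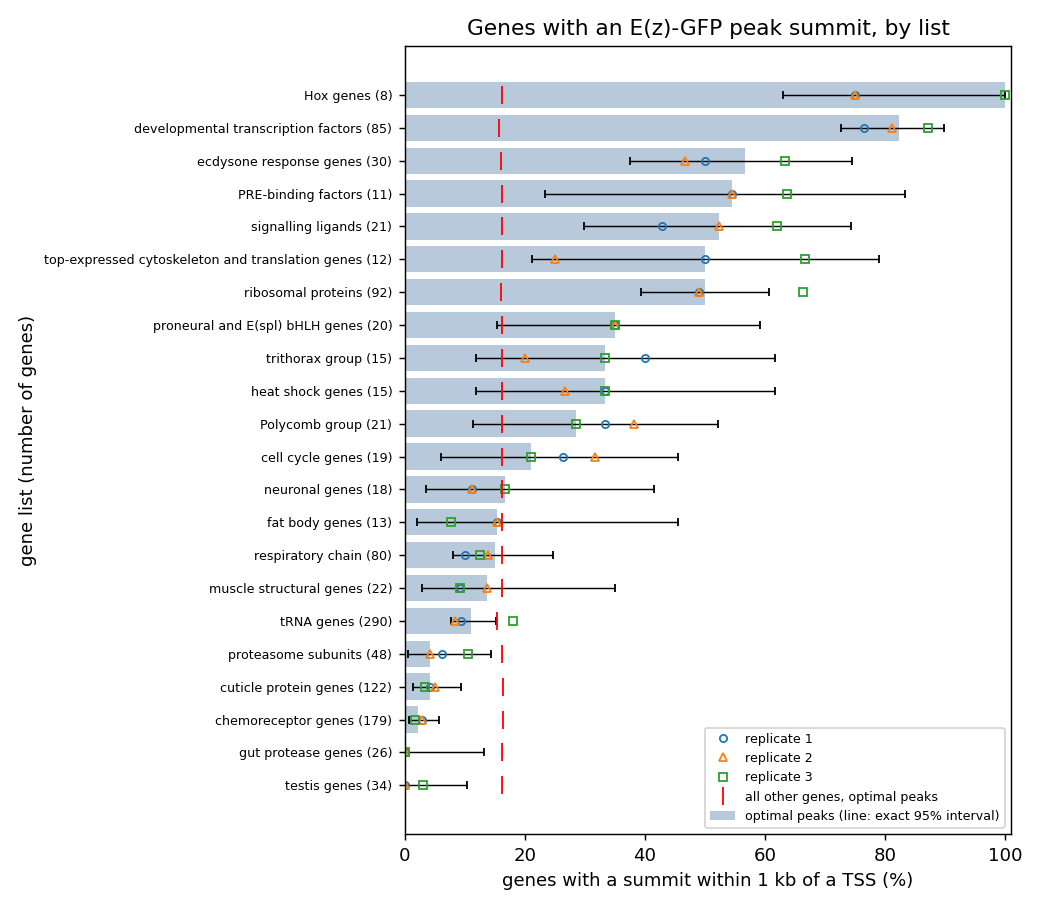
Percent of the genes of each fixed list with a summit within 1 kb of a TSS, with the number of genes in brackets. Bars are the optimal list with exact 95% binomial intervals, open symbols are the replicates and red ticks are all other genes. Hox genes are at 100% and developmental transcription factors at 82.4%.

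Both Hox clusters held more peaks per Mb than the genome, and the excess passed the test in the bithorax complex. From Ubx to Abd-B, at 3R 16656623 to 16972236, the optimal list had 38 peaks, 120 per Mb against 42.0 for the genome (one-sided permutation p = 0.0147 over 100000 random windows). The replicates' lists gave 121 ± 21.1 per Mb (SD, n = 3). The strongest summits there were at 16948797 in an intron of Abd-B, at 16869541 in an intron of MSAmiP and at 16811929 in an intron of abd-A, with optimal ranks of 146, 151 and 160. The best promoter peak of abd-A had a mean rank of 1111 ± 794 (SD, n = 3), that of Abd-B 962 ± 220 and that of Ubx 9175 ± 6050. From lab to Antp, at 3R 6661427 to 6999228, there were 32 peaks, 94.7 per Mb (one-sided permutation p = 0.0569), and 78.0 ± 10.4 per Mb (SD, n = 3) in the replicates' lists. There the promoter peak of Dfd, 208 bp upstream of the gene, had a mean rank of 316 ± 246 (SD, n = 3), those of pb and lab 824 ± 271 and 888 ± 915, that of Scr 1607 ± 1096 and that of Antp 7107 ± 2115.

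**Figure D2:**
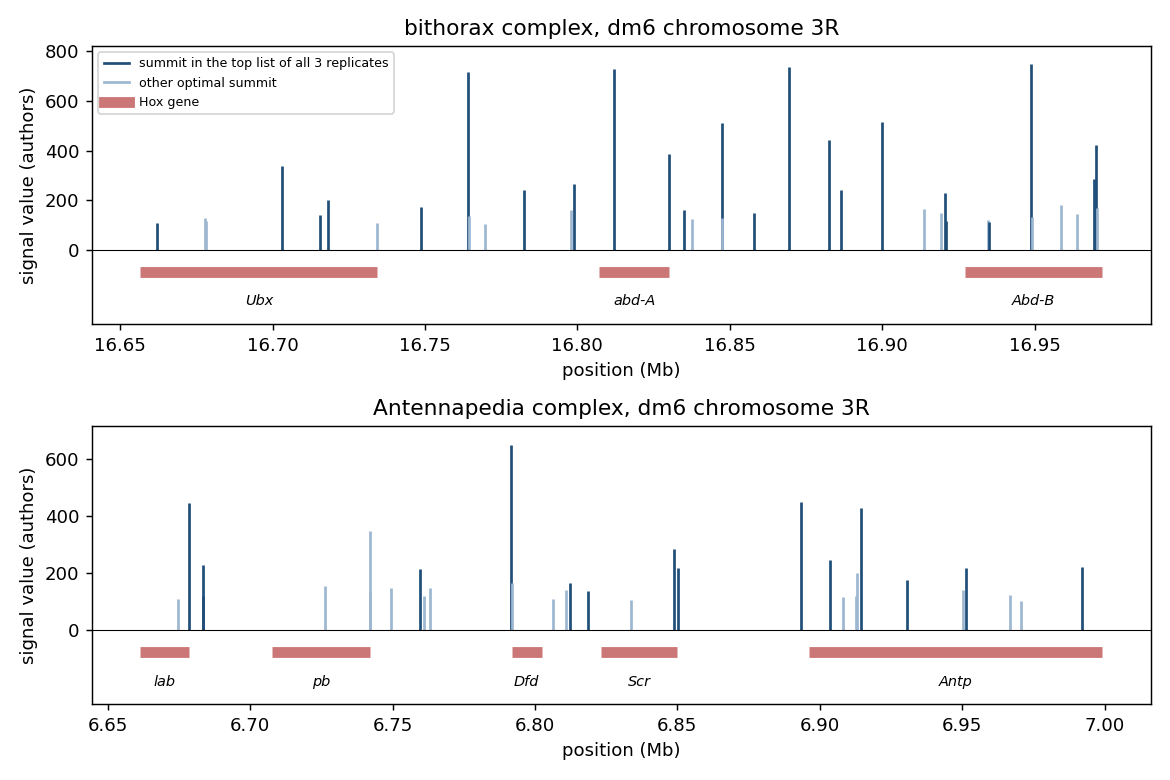
Optimal summits across the bithorax complex and the Antennapedia complex on dm6 chromosome 3R, with position in Mb and the authors' signal value as height. Dark lines are summits in the strong lists of all 3 replicates, pale lines the other optimal summits and red blocks the Hox genes. The bithorax complex holds 38 summits and the Antennapedia complex 32.

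GAGAG, the site of GAGA factor, had the highest ratio of shares among the fixed motifs, and GAAAA, the Dsp1 site, the highest ratio of discordant pairs. The ratio of shares cannot rise far for a motif that the great majority of control windows hold. GAGAG was within 250 bp of 59.0% of 4528 summits and in 44.3% of their control windows 2 kb away, a ratio of 1.33 (exact McNemar test, adjusted p = 7.27e-45), and by this ratio ranked 2 among all words of 5 bases. Pairs with GAGAG at the summit only were 1.85 times as many as pairs with it in the control only. YGAGYG, the Zeste site, was at 60.7% against 51.3% (ratio 1.18, exact McNemar test, adjusted p = 1.41e-19), though not with windows of 100 bp each side (adjusted p = 0.176). GTGTG, the Combgap site, was at 68.8% against 59.7% (ratio 1.15, adjusted p = 2.02e-19, exact McNemar test), and GAAAA at 95.2% against 88.1% (ratio 1.08, discordant ratio 2.73, adjusted p = 1.19e-34, exact McNemar test). With promoters of matched GC content as control the order of discordant ratios turned, 1.95 for GAGAG and 1.60 for GAAAA. Among all words of 5 bases GAAAA ranked 85 by the ratio of shares. By odds ratio it ranked 5 (2.66), below AAAAA (4.37), AAAAT (3.44), TAAAA (2.86) and AAATA (2.83). Its excess is therefore shared with other A-rich words and is not particular to the Dsp1 site. GCCAT, the core of the Pho site, was at fewer summits, 59.1% against 66.1% (ratio 0.894, exact McNemar test, adjusted p = 7.66e-12), and by this ratio ranked 422 among the words of 5 bases. With promoters of matched GC content as control it was at 59.6% against 62.8% (ratio 0.949, exact McNemar test, adjusted p = 5.07e-04). Only this core of 5 bases was searched, and most control windows hold it, so its share is no count of Pho sites. RRGGYG, the Spps site, was at 68.5% against 69.6% (exact McNemar test, adjusted p = 0.284), and with promoters of matched GC content as control its ratio was 1.06 (exact McNemar test, adjusted p = 1.31e-05). With 100 bp each side RRGGYG was at fewer summits than control windows (ratio 0.783, exact McNemar test, adjusted p = 5.58e-17).

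**Figure D3:**
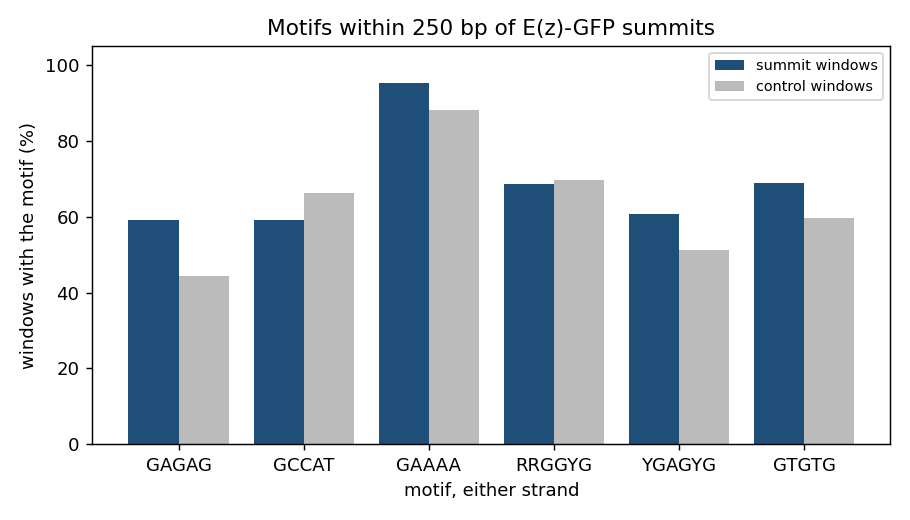
Percent of summit windows and control windows, 250 bp each side, with each motif on either strand, over 4528 summits. GAGAG is at 59.0% of summit windows and 44.3% of control windows.

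The E(z) gene itself, at 3L 10634575 to 10638130, had a peak in replicates 1 and 2 only. The replicate 1 peak, at 3L 10637836 to 10638186, ranked 61 of 30000, and the replicate 2 peak, at 3L 10638016 to 10638170, ranked 225. Replicate 3, the pooled list and the optimal list had 0 summits within 1 kb of the gene, and the nearest optimal summit was 9132 bp away. The fusion is a transgene of this gene, so reads from the endogenous copy and from the transgene cannot be told apart in these lists.

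On dm3, an earlier assembly, the authors' optimal list held 5371 peaks against 5623 on dm6, with a median width of 420 bp against 424 bp. The share found in all 3 replicates was 56.0% on dm3 and 55.9% on dm6. On dm3, 6 optimal peaks lay off the 6 arms, and on dm6 0 did. No coordinates were converted between assemblies.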

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

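The promoter share and the bithorax complex density kept their direction and their side of the threshold in all alternatives run, as did the call that the Antennapedia complex did not pass. The share found in all 3 replicates was 43.9% with reciprocal overlap of 50% and 84.9% with the top 2N peaks. Leaving out a replicate gave pairwise overlaps from 63.3% to 75.6% and rank correlations from 0.537 to 0.759, with the highest of each without replicate 3. The number of arms past the threshold was 2, and it was 1 among the peaks found in all 3 replicates, 4 with the share of genes as expectation, and from 1 to 3 when a replicate was left out. The number of lists past the threshold was 12 and ranged from 8 to 14 over the alternatives. Over 220 combinations of list and alternative, 153 kept direction and call, 34 lost the call, 14 gained it and 19 changed direction. Over 48 of motif and alternative, 44 kept both.

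None of the arms or lists that changed direction had passed the test in the first place, and the cause was not tested. With gene share as expectation, 2L (18.0%) fell below it. On dm3 the expected shares came from the highest peak end of each arm and differed from those on dm6. There X (18.5%) and 2L (18.1%) fell below the expected share, while 3R (23.8%) rose above it. Trithorax genes were at 6.67% in the higher-signal peaks, against 9.91% of other genes. Against circular shifts, respiratory chain (15%), muscle (13.6%), fat body (15.4%) and transfer RNA genes (11.03%) lay above the shifted means of 7.76%, 11.1%, 7.83% and 7.22%. Those means come from shifted peaks, which lie at promoters less often, and not from other genes. When a replicate was left out, cell cycle genes ranged from 10.5% to 15.8% and changed direction at 10.5% only, without replicates 2 and 3. Fat body genes ranged from 7.69% to 15.4% and changed at 15.4% only, without replicate 3, and neuronal genes were at 11.1% and changed without replicates 1 and 3. At 500 bp, cell cycle, muscle and fat body genes were at 10.5%, 13.6% and 15.4%, and at 5 kb neuronal, fat body and transfer RNA genes were at 22.2%, 46.2% and 40.7%. With gene bodies, muscle and fat body genes were at 22.7% and 30.8%, and with the nearest gene only muscle genes were at 18.2%. The RRGGYG ratio was 1.06 with GC-matched promoters. Of these, only transfer RNA genes at 5 kb and RRGGYG passed the test in the changed direction. With TSSs of all annotated genes, chosen after seeing the data, the promoter share was 45.9%. Depth is unknown, so what it limits was not assessed.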

Other observations

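Some strong replicate peaks had no pooled peak over their summit. Among each replicate's 1000 highest-signal peaks, 42 of replicate 1, 22 of replicate 2 and 22 of replicate 3 were of this kind (mean 2.87% ± 1.15, SD, n = 3). The E(z) peaks of replicates 1 and 2 were among them, at ranks 61 and 225. The optimal list is a subset of the pooled list and so holds none of them.

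The words most enriched at summits were not limited to the fixed motifs. The ratio of shares cannot be high for words that the great majority of control windows hold. By this ratio CACTG ranked 1 among all words of 5 bases, at 75.9% of summit windows against 56.7% of control windows, above GAGAG at 59.0% against 44.3%. By odds ratio AAAAA ranked 1 (4.37), CACTG 7 (2.41) and GAGAG 19 (1.81). The share of summits with GAGAG was 69.1% in the 563 strongest optimal peaks and 61.2% in the 562 weakest, with no steady fall between, since bins of lower signal than the first held as little as 52.5%. No test was made of these ranks.

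The tests of signal at highly transcribed loci, with its comparison among promoter peaks, of high transcription in general, of nearest genes and of orders without a ceiling were chosen only after the results were seen. Of the 25 strongest shared peaks, 0 had a Hox or developmental transcription factor gene from the fixed lists as the nearest gene. From the 541 shared peaks among the 563 strongest 1.25 were expected, so the count decides nothing. Summits with the DNA replication-related element within 250 bp were 3.02% of the 562 strongest peaks and 2.56% of the 2812 weaker peaks, a ratio of 1.18 (95% bootstrap interval 0.658 to 1.91). The ratio was just under the bound set beforehand and the interval was wide. It argues only against a large excess of the exact sequence TATCGATA, the only one searched for this question. Those near a transposable element were 0.356% against 1.28%, a ratio of 0.278 (95% bootstrap interval 0 to 0.790). That argues against such elements as the source of the strongest peaks, though the share among the strongest rests on few peaks. Peaks at ribosomal protein or top-expressed genes had a median rank percentile of 40.7 (95% bootstrap interval 32.8 to 45.7, where 0 is the strongest), between the bounds set beforehand, so high transcription stays open. Peaks at developmental and Hox genes ranked above other promoter peaks, with a median percentile of 29.4 against 46.0, a difference of -16.6 (permutation p = 4.9e-04). The permutation treated peaks as independent, though a gene such as Abd-B has several summits within 1 kb of a TSS, so this p may be too small. Polycomb repressive complex 2 at its target genes stays a candidate explanation for the rank of those promoter peaks, not of all strong peaks. Summits within 1 kb of a developmental transcription factor gene's TSS were 3.55% of the 563 strongest peaks and 0.890% of the 562 weakest. Counted instead as the nearest gene at any distance, Hox or developmental transcription factor genes were at 4.80% of the 563 strongest and 6.23% of the 562 weakest.

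Replicate 3 lay apart from replicates 1 and 2. Its 453 strong peaks that neither other relaxed list held were at promoters in 77.3%, against at most 27.6% in 1000 circular shifts (permutation p = 0.001, the smallest the shifts can give). That argues against peaks placed at random along the arms. Background of a weaker library that itself favours promoters was not tested, so library quality stays open. Of 1509 peaks strong only in replicate 3, 2.58% were near ribosomal protein, transfer RNA or top-expressed genes. Of 1079 peaks strong in both replicates 1 and 2 and not in 3, 0.371% were, a ratio of 6.97 (95% bootstrap interval 3.04 to 30.8). Promoters in general were also more frequent among the former, 63.7% against 34.2% (ratio 1.86), and among promoter peaks alone the ratio was 3.74 (95% bootstrap interval 1.64 to 16.1). These ratios set peaks of a single replicate against peaks shared by replicates 1 and 2, and the low share of the latter rests on few peaks. Peaks strong only in replicate 1 or only in replicate 2 were not compared, so the ratios cannot be tied to replicate 3. The higher ribosomal and transfer RNA shares of replicate 3 had been seen before these lists were chosen, so the ratios do not count for more signal at highly transcribed loci, which stays open, and no biological explanation was tested, since the design has 1 group.

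Ribosomal protein genes held summits more often than other genes. With each peak given only to the nearest gene the odds ratio was 4.64 (95% interval 3.09 to 7.00), which argues against peaks of neighbouring genes. Proteasome and respiratory chain genes together were at 10.9% (exact 95% interval 6.11% to 17.7%) against 16.2% of other genes, and since that interval includes the latter share, high transcription in general may still contribute. Transcription of these genes was not measured, and their lists hold every gene with a matching symbol, whatever its expression.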
